A study of Homo sapiens with 8 samples.

How the data were processed

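RNA from Saos-2 cells was measured on 8 Affymetrix 3′ expression arrays, 1 array per sample, from biotin-labelled cRNA per the labels' protocols. The deposited values are probe-set intensity on a linear scale, made by the authors with MAS5 per the submitters' processing notes. The MAS5 version and settings were not given in the sources used here. MAS5 summarises the probes of a probe set into 1 signal and scales each array to a common level. In the deposited table the 2% trimmed mean was 100.01 on every array, and single signals ran from 0.0213 to 10402.1. The number of arrays limits the precision of each value.

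Groups came from the labels: untreated (3 arrays, replicates 1, 2 and 3), treated for 6 h (3 arrays, replicates 1, 2 and 3) and treated for 12 h (2 arrays, replicates 1 and 3). A 12 h replicate 2 was not analysed here. Nothing in the labels says whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except those named below as added. No 2 arrays shared more than 1 identical value among the 54675 probe sets.

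The table held 54675 probe sets, of which 62 were controls and were left out. A platform annotation gave 1 gene symbol for 41091 probe sets and several for 1801, and 11721 were not listed in it and stayed unnamed. Genes were represented by the brightest of their probe sets with 1 symbol, which gave 19775 genes. Signals under the 10th percentile of all values (2.385) were set to it before log2 was taken, so fold changes of dim genes are understated. A gene was tested if its mean log2 signal over the 8 arrays exceeded the median of all probe sets (4.216), which left 12063 genes. No coordinates were used here.

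Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a variance trend), with the 3 groups in 1 fit and, for treated against untreated, 2 groups of 5 and 3 arrays. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Gene lists, 33 in number and written from textbook knowledge, were tested with limma's camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of each comparison. Lists with under 5 tested genes were not tested, which left 29. Some genes stand in several lists, SLC7A11 among the NRF2 and ATF4 lists for example. For a pair of arrays with the same replicate number, a list's median was placed among 10000 random lists matched on expression in 20 bins.

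Named genes followed a rule. Where fewer than 5 genes passed the threshold in a comparison, it took the 5 largest rises and 5 largest falls among the 50 smallest p-values, named as not passing. To these it added a fixed set, of which are reported TP63, TP73, CDKN1A, MDM2, BAX, BBC3, PMAIP1, HMOX1, TXNRD1, GCLM, SLC7A11, ATF3, DDIT3, TRIB3, HSPA1A, DNAJB1 and HSPA5, and up to 4 members of each list with the smallest p. Which lists are described beyond those that passed, and how many members of a list are named, was settled after the values were seen. TP63, BBC3 and HSPA1A had no probe set of their own in the annotation and were not analysed here. A part of the fixed set and of the lists is not reported here. TP73 fell under the filter and was not tested. Probe sets of metallothioneins, histones and tubulins can share sequence, so single members of these families are uncertain.

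Same-numbered arrays deviated together. The correlation across genes of their deviations from the group means was 0.108 to 0.637 in the 7 same-numbered pairs, against -0.576 to 0.333 in the 14 others, so the numbers were taken to pair the samples, and each fit was repeated with the replicate number as a block. Deviations within a group sum to 0, and those of the 2 12 h arrays mirror each other, so a part of this contrast is built in. The pairing under number 1 is weakly shown: 12 h replicate 1 correlated at 0.333 and 0.295 with the replicate 2 arrays, but at 0.108 and 0.159 with the other replicate 1 arrays. Other repeats of the analysis, chosen beforehand, used quantile normalization, centring each array on its median, a lower floor at a signal of 1, and a pseudocount of 32. They also used no filter and a filter at the 75th percentile, averaged or single probe sets, and no variance trend. The rest used only the groups compared, camera with an estimated correlation, and each array left out in turn. After the data were seen, fits without both replicate 2 arrays and fits with limma's array weights were added, each also with the block.

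The scripts were tested on simulated data, with 10 simulations of 200 changed genes each. For 6 h against untreated (12132 genes) 1.79% of 2-fold, 50.4% of 4-fold and 62.9% of 8-fold changes were recovered, and 45.5%, 72.7% and 76.7% with the block. For 12 h against untreated (12135 genes) these were 1.19%, 43.4% and 61.4%, and 37.6%, 69.3% and 78.0% with the block. For 12 h against 6 h (12135 genes) they were 1.04%, 41.5% and 62.4%, and 38.2%, 69.1% and 77.6%. For treated against untreated (12130 genes) they were 9.85%, 53.6% and 59.5%, and 50.4%, 70.4% and 68.0%. Genes left unchanged were called at most 2 times in all 10 simulations of a comparison without the block and 104 to 134 times with it. A shift of 0.34 in the ATF4 list, a size taken from the real data, was called in 10 of 10 simulations in every comparison over 12063 genes. With no planted shift, over 10 simulations, list calls without and with the block numbered 16 and 0 at 12 h against 6 h, 7 and 1 at 12 h against untreated, 0 and 1 at 6 h against untreated, and 2 and 2 in treated against untreated cells. Spread beyond the replicate effects was drawn independently for each probe set. These list counts therefore do not cover lists whose genes vary together in other ways, and they do not vouch for the list calls with the block. Camera with an estimated correlation was not run on simulated data, so how often it would call a real shift is unknown. Its p also rose where the estimate was negative. For interferon-stimulated genes at 12 h (estimate -0.0542) camera gave p = 0.0224 at the preset and p = 0.058 at the estimated correlation. A call lost in this setting therefore does not by itself show that genes varying together made the call.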

Results

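Saos-2 is an established human osteosarcoma line. The study asked how gene expression across the genome responds in these cells to a compound labelled Prima, given for 6 h or 12 h. Untreated cells (3 arrays), cells treated for 6 h (3 arrays) and cells treated for 12 h (2 arrays) were profiled, and values below are MAS5 signals scaled to a 2% trimmed mean of 100.01 on every array.

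The replicate 2 arrays stood apart from the others. Median signal was 50.9 on untreated replicate 2 and 47.5 on 6 h replicate 2, against 14.2 to 24.95 on the 6 other arrays. On the replicate 2 arrays 0.0623% and 0.0714% of probe sets lay at or under the floor, against 6.26% to 20.8% elsewhere, and no 12 h array carries that number. The ACTB 3′ to 5′ signal ratio, a sign of RNA integrity, was 2.29 on 12 h replicate 1 and 1.73 on 6 h replicate 1, and 1.125 to 1.38 on the others. The same ratio for GAPDH did not set these arrays apart. It ran from 0.927 to 1.038 over the 8 arrays, with 1.038 on 12 h replicate 1 and 0.978 on 6 h replicate 1. Across probe sets, Pearson's r had a median of 0.894 between arrays of the same number and different groups, 0.7997 between arrays of the same group and different numbers and 0.802 between arrays that differ in both (genes are not independent replicates). The lower medians come from the replicate 2 arrays, whose r with any other array was 0.780 to 0.830, and among the others same-group r was 0.8766 to 0.9003, near the 0.8749 to 0.8939 of the replicate 1 arrays with each other and under the 0.9552 to 0.957 of the replicate 3 arrays.

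**Figure D1:**
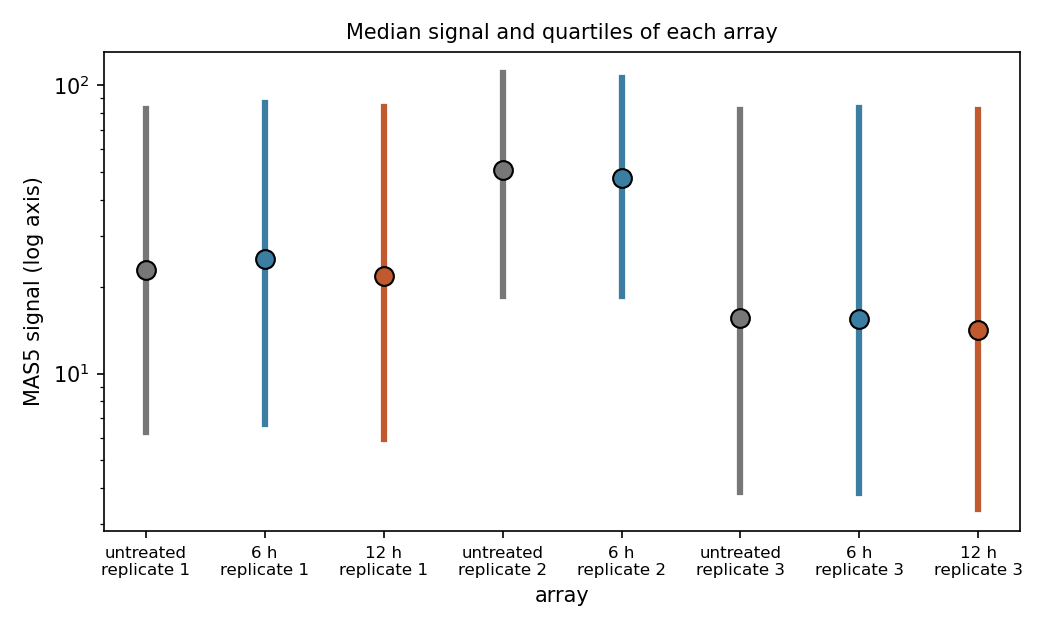
Median MAS5 signal (points) and quartiles (bars) of all probe sets on each of the 8 arrays, on a log axis. The replicate 2 arrays have medians of 50.9 and 47.5, above the range of 14.2 to 24.95 on the other 6.

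The first comparison asked what differed after 6 h. RNF25, a RING-type ubiquitin ligase, had a mean signal of 71.4 ± 19.4 (SD, n = 3) after 6 h and 21.6 ± 3.24 (SD, n = 3) in untreated cells, a log2 difference of 1.70 ± 0.63 (SE). SEMA6D, a semaphorin, stood at 124.5 ± 118 (SD, n = 3) against 31.9 ± 13.3 (n = 3), and MAN2B1, a lysosomal mannosidase, at 67.2 ± 6.88 (n = 3) against 29.4 ± 20.7 (n = 3). PPP6R2 and CLDN15 had log2 differences of 1.595 ± 0.60 and 1.53 ± 0.60 (SE), although neither of 2 other PPP6R2 probe sets went the same way. On the other side stood PAGE5, a cancer-testis antigen, at 27.7 ± 33.0 (SD, n = 3) against 79.4 ± 17.5 (n = 3), and ZNF23, a zinc finger protein, at 15.6 ± 12.3 against 49.5 ± 6.13. BAZ2B-AS1, DENND2A and SLC16A9 had log2 differences of -2.74 ± 1.03, -1.77 ± 0.72 and -1.74 ± 0.67 (SE). None of these genes passed the test. With limma, 0 genes were higher and 0 lower (smallest adjusted p 0.9999), and 79 of 12063 had an unadjusted p under 0.05 (39 higher, 40 lower) where 603 were expected by chance. With the replicate block the count was again 0, with 493 genes at an unadjusted p under 0.05, and with array weights it was 0 with 360. The arrays of both groups did not overlap in 3.54% of genes, against 10% by chance if arrays were exchangeable, which same-numbered arrays that deviate together are not, and the median SE was 0.352.

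At 6 h, no gene with a known role in stress or cell cycle arrest passed the test. CDKN1A, a cell cycle inhibitor, averaged 183 ± 89.0 (SD, n = 3) against 131 ± 14.0 (n = 3), with 283.5 on 6 h replicate 1. MDM2, a ubiquitin ligase, averaged 373.5 ± 63.6 against 463 ± 96.9, and the log2 differences of the BCL2 family members BAX and PMAIP1 were -0.01 ± 0.37 and 0.19 ± 0.54 (SE). The stress transcription factors DDIT3 and ATF3 differed by 0.52 ± 0.37 and 0.30 ± 0.35, and TRIB3 by 0.33 ± 0.49. HMOX1, TXNRD1, GCLM and SLC7A11, which serve antioxidant defence, differed by 0.10 ± 0.345, 0.165 ± 0.30, 0.11 ± 0.22 and -0.03 ± 0.33. The chaperones DNAJB1 and HSPA5 both differed by 0.21, with SEs of 0.24 and 0.25. TP73, a transcription factor, was too dim to test, at 17.2 ± 8.82 (SD, n = 3) against 21.6 ± 13.6 (n = 3).

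No gene list passed at 6 h. The 31 tested cytosolic ribosomal protein genes came closest, with 27 above 0 and a median log2 difference of 0.13 (camera adjusted p = 0.0996, and adjusted p = 0.948 with an estimated correlation). RPS23 differed by 0.235 ± 0.21 (SE) and RPS24 by 0.23 ± 0.23. With the replicate block the list passed (adjusted p = 4.9e-07, and adjusted p = 0.702 with an estimated correlation), and after quantile normalization its median was 0.02. Of 15 histone genes 11 were below 0 (median -0.13, adjusted p = 0.132, and 0.0381 with the block, but adjusted p = 0.948 and 0.702 with an estimated correlation), with H4C8 at -0.64 ± 0.39 and H2AC6 at -0.54 ± 0.36. Of 20 cholesterol genes 16 were below 0 (median -0.125, adjusted p = 0.132), with the synthesis enzymes EBP at -0.36 ± 0.25 and IDI1 at -0.39 ± 0.28. Of 35 ATF4 and amino acid response genes 21 were above 0 (median 0.09, adjusted p = 0.538). Among them STC2, a secreted glycoprotein, reached 706.1 on 6 h replicate 1 but 169.2 and 109.3 on the other 6 h arrays, and SHMT2, of mitochondrial serine metabolism, differed by -0.37 ± 0.26. Of 21 NRF2 target genes 13 were above 0 (median 0.10, adjusted p = 0.538), with SRXN1, the sulfiredoxin that repairs peroxiredoxins, at 318 ± 6.23 (SD, n = 3) against 219 ± 59.5 (n = 3). The remaining lists had adjusted p from 0.386 to 0.988, and 0 members of any list passed when adjusted over the list alone.

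Leaving out 1 array moved these list counts. Without untreated replicate 3, 6 lists were higher, without 6 h replicate 2, 4, and without 6 h replicate 1, 1. The ribosomal list passed in each of these cases, with medians of 0.28, 0.19 and 0.19 (adjusted p = 5.31e-09, 0.0145 and 5.35e-05). Without untreated replicate 2, 5 lists were lower and without 6 h replicate 3, 3, and the histone list passed in both cases with medians of -0.40 and -0.38 (adjusted p = 0.00109 and 0.000184).

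The second comparison asked what differed after 12 h. ATF4 and amino acid response genes rose together: of 35 tested, 31 were above 0, the median log2 change was 0.34 and camera gave an adjusted p of 1.62e-05 (adjusted p = 0.373 with an estimated correlation). SLC7A11, the cystine transporter subunit, averaged 442 ± 182 (SD, n = 2) against 235.5 ± 23.4 (n = 3), 1.80-fold, and ASNS, asparagine synthetase, 308.5 ± 39.5 (n = 2) against 193 ± 49.7 (n = 3), 1.63-fold. ATF4 itself, the transcription factor of the amino acid response, averaged 1446 ± 26.0 (n = 2) against 1053 ± 198 (n = 3), 1.39-fold, and the cysteinyl-tRNA synthetase CARS1 804 ± 73.7 against 563 ± 146, 1.46-fold. None of the members passed as a single gene, either over all genes or adjusted over the list alone. Within pairs of arrays of the same number, the list's median was 0.34 in replicate 1 (29 of 35 above 0) and 0.28 in replicate 3 (31 of 35), each above nearly all random lists, and 0.13, -0.07 and 0.04 in the 6 h pairs. Random lists do not keep how genes of a list vary together, so extreme places also arose in lists that moved opposite ways. NRF2 targets lay above 1.4% and 100% of random lists in the 12 h pairs, and metallothioneins above 0%, 100% and 99.7% in the 6 h pairs. With the replicate block the median was 0.34 (adjusted p = 2.3e-06, and adjusted p = 0.243 with an estimated correlation). Without 12 h replicate 3 the median was 0.40 and the list no longer passed (adjusted p = 0.075). Without 12 h replicate 1, the array with the ACTB ratio of 2.29, it was 0.36 and the list passed (adjusted p = 1.83e-06). Array centring on the median moved all genes by a median of 0.66 at 12 h, against 0.08 as deposited. Relative to all genes the list stood 0.25 higher under both, which centring cannot change because it shifts every gene of an array alike. After quantile normalization it stood 0.21 higher.

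**Figure D2:**
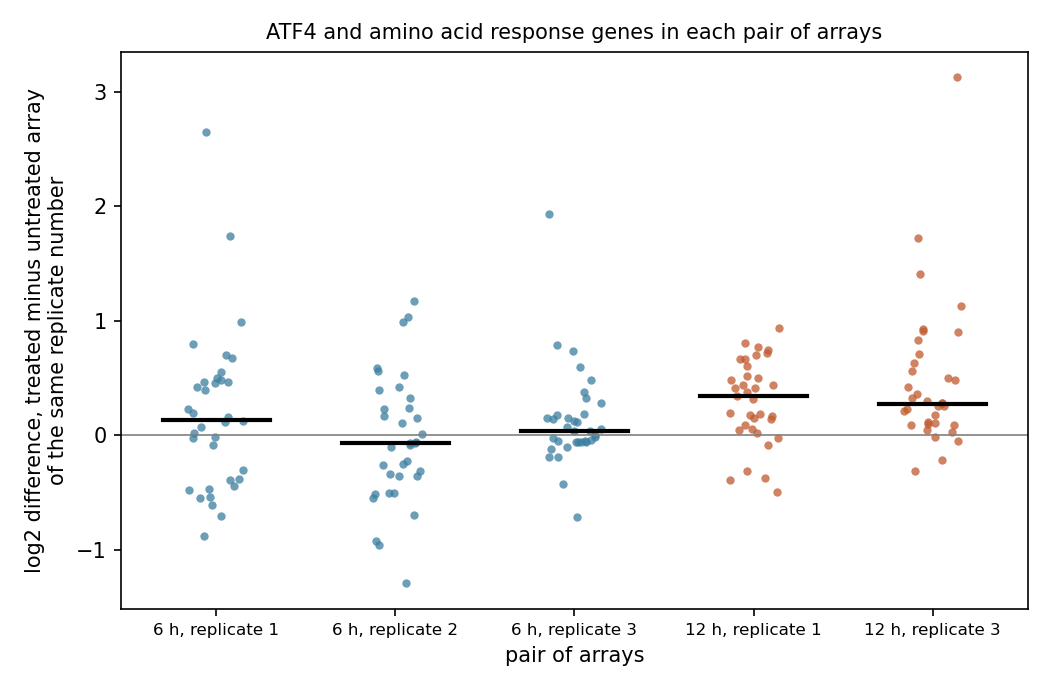
Log2 difference of each of the 35 tested ATF4 and amino acid response genes (points) between a treated and the untreated array of the same replicate number, for the 3 pairs of 6 h and the 2 pairs of 12 h, with the median as a bar. The medians are 0.34 and 0.28 in the 12 h pairs and 0.13, -0.07 and 0.04 in the 6 h pairs.

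A further 8 lists rose at 12 h without the block. NRF2 target genes, which serve antioxidant defence, had 20 of 21 members above 0 (median 0.22, adjusted p = 0.018), with SRXN1 at 345 ± 28.3 (SD, n = 2) against 219 ± 59.5 (n = 3) and the pentose phosphate enzyme TKT at 1185 ± 149 against 920 ± 15.9. SLC7A11 is also a member. Heat shock genes had 17 of 18 above 0 (median 0.195, adjusted p = 0.0198), with the chaperones DNAJB1 and HSPH1 1.44-fold and 1.41-fold higher and the co-chaperone BAG3 1.54-fold. Metallothioneins and the zinc exporter had 7 of 8 above 0 (median 0.40, adjusted p = 0.0345), with MT2A at 1.68-fold and MT1X at 1.61-fold, members that share sequence. G1/S genes had 29 of 33 above 0 (median 0.19, adjusted p = 0.0345), with E2F2 at 0.60 ± 0.37 (SE) and the origin recognition subunit ORC1 at 0.45 ± 0.33. G2/M genes had 31 of 36 above 0 (median 0.22, adjusted p = 0.0239), with the phosphatase CDC25B at 0.45 ± 0.31 and the kinetochore protein CENPF at 0.40 ± 0.32. Oxidative phosphorylation genes had 31 of 34 above 0 (median 0.17, adjusted p = 0.0345), with NDUFB3 at 0.50 ± 0.42 and NDUFS4 at 0.38 ± 0.35. Proteasome genes had 24 of 27 above 0 (median 0.17, adjusted p = 0.0345), with PSMD1 at 0.59 ± 0.32 and PSMD2 at 0.50 ± 0.31. Cytosolic ribosomal protein genes had 30 of 31 above 0 (median 0.175, adjusted p = 0.0198), with RPL19 at 0.29 ± 0.27 and RPS7 at 0.22 ± 0.23, but after quantile normalization the list lay 0.04 under the median of all genes (-0.04). With an estimated correlation none of the 8 passed (adjusted p = 0.844 for each), and 0 members passed adjusted over the list alone.

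With the replicate block, ribosomal genes still passed (median 0.10, adjusted p = 0.00219, and adjusted p = 0.892 with an estimated correlation) and the others of these 8 lists did not. Their blocked medians were 0.11 for NRF2 targets (adjusted p = 0.419), 0.08 for heat shock (0.116), 0.11 for metallothioneins (0.599), 0.06 for G1/S (0.895), 0.08 for G2/M (0.611), 0.015 for oxidative phosphorylation (0.844) and -0.002 for the proteasome (0.934). The count of 9 higher lists became 0 without 12 h replicate 3, 1 without untreated replicate 2, 4 without untreated replicate 1 and 14 without 12 h replicate 1. Without both replicate 2 arrays, a fit added after the data were seen, it was 1. A single list was lower without 6 h replicate 1 and without 12 h replicate 1, against 0 with all arrays. Without untreated replicate 2, medians were 0.13 for NRF2 targets, 0.13 for heat shock, 0.06 for metallothioneins, -0.01 for G1/S, 0.05 for G2/M, 0.02 for oxidative phosphorylation, 0.09 for ribosomal and 0.02 for proteasome genes. Without 12 h replicate 3 they were 0.06, 0.05, 0.17, 0.17, 0.10, 0.06, 0.02 and 0.04 in the same order. Without 12 h replicate 1 they were 0.41, 0.41, 0.58, 0.20, 0.25, 0.30, 0.31 and 0.30, and without untreated replicate 3 0.24, 0.28, 0.64, 0.31, 0.31, 0.29, 0.34 and 0.30, and all 8 lists passed in both cases. Without untreated replicate 1, heat shock (0.19), G2/M (0.19), oxidative phosphorylation (0.19), proteasome (0.16, each with an adjusted p of 0.113) and ribosomal genes (0.08, adjusted p = 0.665) lost their calls. Within the pairs of 12 h arrays, NRF2 targets had a median of -0.10 in replicate 1 and 0.27 in replicate 3, and ribosomal genes 0.17 and -0.01.

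**Figure D3:**
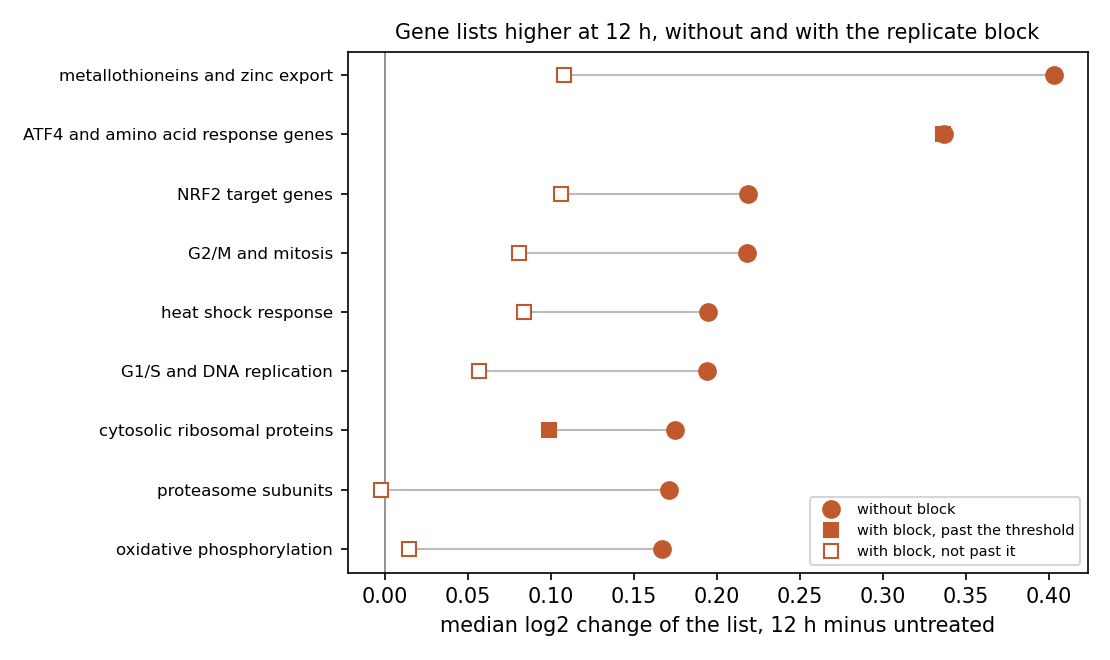
Median log2 change of the 9 gene lists that passed at 12 h against untreated cells, without the replicate block (circles) and with it (squares, filled where the list still passed). ATF4 and amino acid response genes stand at 0.34 in both fits, ribosomal genes move from 0.175 to 0.10, lying at -0.04 relative to all genes after quantile normalization, and the 7 others do not pass with the block. Calls shown are at the preset correlation, and with an estimated correlation none of the 9 passed in either fit.

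Single genes at 12 h did not pass. GRPR, the gastrin-releasing peptide receptor, averaged 5.18 ± 1.22 (SD, n = 2) against 66.5 ± 35.4 (n = 3), a log2 difference of -3.50 ± 0.87 (SE). AIM2, a cytosolic DNA sensor, averaged 8.73 ± 8.06 (n = 2) against 57.6 ± 42.4 (n = 3), and the non-coding ADIRF-AS1, LINC01920 and NRSN2-AS1 differed by -3.07 ± 1.23, -3.02 ± 1.21 and -3.02 ± 1.18. KLC4, a kinesin light chain, averaged 58.8 ± 11.1 (n = 2) against 16.3 ± 9.12 (n = 3), and OTULIN, a linear-ubiquitin deubiquitinase, 121 ± 4.41 against 45.65 ± 23.2. TRAPPC12, MAN2B1 and ZNF580 differed by 1.57 ± 0.67, 1.46 ± 0.63 and 1.27 ± 0.53. With limma 0 genes were higher and 0 lower (smallest adjusted p 0.9999), 74 had an unadjusted p under 0.05 (33 higher, 41 lower), and non-overlapping groups made up 14.5% of genes against 20% by chance. The block left the count at 0 with 262 genes under an unadjusted 0.05, and array weights left it at 0 with 634 (smallest adjusted p 0.296).

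Single genes of cell cycle arrest, of apoptosis and of stress did not pass at 12 h. CDKN1A averaged 114 ± 2.09 (SD, n = 2) against 131 ± 14.0 (n = 3), and MDM2, BAX and PMAIP1 differed by 0.15 ± 0.29, 0.245 ± 0.409 and 0.38 ± 0.60 (SE), with none of 5 other MDM2 probe sets going the same way. ATF3 differed by 0.68 ± 0.39, with neither of 2 other probe sets going the same way, DDIT3 by -0.16 ± 0.42, TRIB3 by 0.09 ± 0.55 and HSPA5 by 0.29 ± 0.28. HMOX1, TXNRD1 and GCLM differed by 0.34 ± 0.39, 0.29 ± 0.33 and 0.20 ± 0.24. TP73 stood at 17.9 ± 11.5 (SD, n = 2). Pro-apoptotic BCL2 genes split 4 to 4 (adjusted p = 0.951), and of 18 caspase, death receptor and IAP genes 11 were above 0 (adjusted p = 0.965). ER chaperone and unfolded protein response genes had 18 of 22 above 0 (median 0.10, adjusted p = 0.369).

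The third comparison set 12 h against 6 h directly. ATF4 and amino acid response genes were higher at 12 h in 28 of 35 cases (median 0.33, adjusted p = 0.000591, and adjusted p = 0.823 with an estimated correlation). SLC7A11 averaged 442 ± 182 (SD, n = 2) against 241 ± 86.3 (n = 3), the amino acid transporter SLC7A5 425 ± 80.7 against 274 ± 64.7, VEGFA, the vascular growth factor, 801.5 ± 123 against 550.5 ± 108, and ASNS 308.5 ± 39.5 against 207 ± 8.91. With the block the list's median was 0.22 (adjusted p = 0.000653, and adjusted p = 0.47 with an estimated correlation). Its call was lost without 6 h replicate 2 (0.20, adjusted p = 0.0885) and without 12 h replicate 3 (0.28, adjusted p = 0.121).

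The other 6 lists higher at 12 h than at 6 h passed only without the block, and none passed with an estimated correlation (adjusted p = 0.968 for each). G1/S genes were higher in 30 of 33 cases (median 0.235, adjusted p = 0.000591, and 0.14 with the block), with the replication factors GINS2 at 0.84 ± 0.445 (SE) and CDT1 at 0.60 ± 0.39. G2/M genes were higher in 34 of 36 (median 0.245, adjusted p = 0.000591, and 0.0555 with the block), with CDC25B at 0.68 ± 0.31 and the mitotic kinesin KIF23 at 0.59 ± 0.33. Histone genes were higher in 14 of 15 (median 0.41, adjusted p = 0.00422, and 0.138 with the block), with H1-2 at 0.99 ± 0.51 and H2AC6 at 0.66 ± 0.41, members of a family that shares sequence. Metallothioneins were higher in 7 of 8 (median 0.495, adjusted p = 0.0432, and 0.555 with the block), with MT1X at 0.90 ± 0.41. Autophagy and lysosome genes were higher in 23 of 25 (median 0.17, adjusted p = 0.0432, and 0.413 with the block), with WIPI1 at 0.78 ± 0.445 and GABARAP, both of autophagosome formation, at 0.39 ± 0.27. SRF and actin genes were higher in 16 of 19 (median 0.23, adjusted p = 0.0432, and 0.0829 with the block), with smooth muscle actin ACTA2 at 7326 ± 419 (SD, n = 2) against 5166 ± 2470 (n = 3), and CNN1 and TAGLN at 1.32 ± 0.81 and 1.10 ± 0.68. The count of 7 higher lists was 0 without 6 h replicate 2, 2 without 12 h replicate 3, 11 without 6 h replicate 3 and 12 without 12 h replicate 1, and with the block it was 1. In the order G1/S, G2/M, histones, metallothioneins, autophagy and SRF, medians were 0.15, 0.12, 0.26, 0.41, 0.10 and 0.20 without 6 h replicate 2, 0.27, 0.12, 0.24, 0.28, 0.11 and 0.25 without 12 h replicate 3, 0.36, 0.32, 0.68, 0.83, 0.29 and 0.29 without 6 h replicate 3, and 0.22, 0.37, 0.66, 0.65, 0.25 and 0.28 without 12 h replicate 1. Without 6 h replicate 1, metallothioneins (0.21, adjusted p = 0.271), histones (0.16, 0.358) and SRF and actin genes (0.08, 0.934) lost their calls. SRF and actin genes lost theirs also without untreated replicate 2 (0.23, 0.0825) and 12 h replicate 1 (0.28, 0.125), and G1/S genes kept theirs without 12 h replicate 3 (0.27, 0.0499). Centring on the median moved all genes by 0.65 in this comparison, against 0.06 as deposited, and 2 lists passed after quantile normalization.

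Between 12 h and 6 h no single gene passed. PAGE5 averaged 92.0 ± 0.380 (SD, n = 2) at 12 h against 27.7 ± 33.0 (n = 3) at 6 h, and the synaptic protein CBLN2, the laminin chain LAMA5, the retinol carrier RBP4 and the deadenylase PAN2 differed by 2.41 ± 1.04, 2.22 ± 0.93, 1.61 ± 0.61 and 1.47 ± 0.615 (SE). GRPR averaged 5.18 ± 1.22 against 38.3 ± 18.4, and GABRR2, LINC00173, IFT140 and RILP differed by -3.15 ± 1.175, -2.76 ± 1.155, -2.66 ± 1.02 and -2.60 ± 1.04. CDKN1A differed by -0.58 ± 0.38, MDM2 by 0.45 ± 0.29, DDIT3 by -0.68 ± 0.42, ATF3 by 0.375 ± 0.389 and DNAJB1 by 0.32 ± 0.27. Neither of 2 other ATF3 probe sets went the same way. BAX, PMAIP1, HMOX1, TXNRD1, GCLM, TRIB3 and HSPA5 lay between -0.24 (TRIB3) and 0.25 (BAX), each within 1 SE. With limma 0 genes were higher and 0 lower (smallest adjusted p 1), 88 had an unadjusted p under 0.05 (44 each way), and with the block 0 passed and 297 had one. Array weights gave 0 genes and 106, and non-overlapping groups made up 11.6% of genes against 20% by chance.

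The last comparison pooled both times, 5 treated arrays against 3 untreated. Cytosolic ribosomal protein genes were slightly higher as a list, with 30 of 31 above 0 and no single member past the threshold (median 0.145, adjusted p = 0.00592, and adjusted p = 0.96 with an estimated correlation). RPS23 averaged 8238 ± 917 (SD, n = 5) against 7106 ± 1270 (n = 3) and RPS7 5361 ± 483 against 4664 ± 715. With the block the ribosomal list passed again (median 0.11, adjusted p = 9.74e-08, and adjusted p = 0.882 with an estimated correlation), but after quantile normalization it lay at -0.02 relative to all genes, and it lost its call without untreated replicate 1 (0.07, adjusted p = 0.687), untreated replicate 2 (0.04, 0.394), 6 h replicate 3 (0.07, 0.44) or 12 h replicate 3 (0.10, 0.339). ATF4 and amino acid response genes were above 0 in 28 of 35 cases (median 0.19, adjusted p = 0.0287, and adjusted p = 0.96 with an estimated correlation). The tRNA synthetases CARS1 and GARS1 averaged 744.5 ± 128 (SD, n = 5) against 563 ± 146 (n = 3) and 995 ± 149 against 790 ± 54.8. The ATF4 list did not pass with the block (0.20, adjusted p = 0.0798), nor without untreated replicate 1 (0.23, 0.214), untreated replicate 3 (0.11, 0.0982) or 12 h replicate 3 (0.19, 0.402). Without both replicate 2 arrays and with the block, a fit added after the data were seen, it passed (0.20, adjusted p = 0.00296). The count of 2 higher lists ran from 0 (without untreated replicate 1 or 12 h replicate 3) through 1 (without untreated replicate 2 or 6 h replicate 3), 4 (without 12 h replicate 1) and 6 (without 6 h replicate 2) to 7 (without untreated replicate 3), and 3 lists were lower without untreated replicate 2. Centring on the median moved all genes by 0.27, against 0.04 as deposited.

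SRXN1 was among the steadier single genes of the pooled comparison, at 328.5 ± 21.1 (SD, n = 5) against 219 ± 59.5 (n = 3), log2 0.62 ± 0.23 (SE), and it did not pass. MAN2B1 averaged 67.2 ± 5.76 against 29.4 ± 20.7, ARMH4 84.7 ± 7.79 against 44.7 ± 37.1, and RELT, a TNF receptor family member, PPP6R2 and CLDN15 differed by 1.52 ± 0.63, 1.45 ± 0.52 and 1.31 ± 0.51. CGAS, the cytosolic DNA sensor, averaged 55.3 ± 24.1 against 113 ± 18.8, PKIB, a protein kinase A inhibitor, 25.3 ± 5.97 against 65.2 ± 23.8, and DELE1, a mitochondrial stress relay, 48.7 ± 18.3 against 94.8 ± 15.1, with other probe sets of DELE1 split. GPR160 and PTX3 differed by -1.95 ± 0.80 and -1.19 ± 0.49. CDKN1A, MDM2, BAX, PMAIP1, HMOX1, TXNRD1, GCLM, SLC7A11, DDIT3 and TRIB3 lay between -0.12 (MDM2) and 0.32 (SLC7A11), each within 1 SE, and ATF3, DNAJB1 and HSPA5 at 0.45 ± 0.30, 0.34 ± 0.21 and 0.24 ± 0.205. For ATF3 and for PPP6R2, neither of 2 other probe sets went the same way. With limma 0 genes were higher and 0 lower (smallest adjusted p 1), 94 had an unadjusted p under 0.05 (69 higher, 25 lower), and the block gave 0 genes with 489. Array weights gave 0 genes with 2384 at an unadjusted p under 0.05 (smallest adjusted p 0.135). Array weights with the block gave 0 genes with 1123 (smallest adjusted p 0.238). Adjusted over the list alone, 0 list members passed, and with the block ICAM1 among NF-kappaB genes (1.69, adjusted p = 0.0497) and ACTB among housekeeping genes (0.245, adjusted p = 0.0439) did. No correction was made across lists and comparisons, so calls this near the threshold could arise by chance. ICAM1 was dim, with a mean log2 signal of 4.58 against the filter of 4.216. Lists of blood, epithelial and endothelial markers had 3, 3 and 1 genes above the filter and anti-apoptotic BCL2 genes 4, too few to test.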

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

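Using the block and quantile normalization to weigh the lists below was chosen after their values were seen, although both settings had been planned, and the rule for single arrays far from the others was planned.

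Between 12 h and 6 h, 7 gene lists differed at the preset correlation: ATF4 and amino acid response genes (median log2 0.333), metallothioneins (0.495), G1/S (0.235), G2/M (0.245), histones (0.412), autophagy and lysosome (0.172) and SRF and actin genes (0.23). With camera at an estimated correlation none of the 7 passed (adjusted p = 0.823 for the ATF4 list and 0.968 for each of the other 6). A hypothesis for the 6 lists other than the ATF4 list is the make-up of the groups, since a replicate 2 array stands in the 6 h group only: with the replicate number as a block 0 of the 6 passed, with medians of 0.228 for metallothioneins, 0.113 for G1/S, 0.115 for G2/M, 0.228 for histones, 0.116 for autophagy and lysosome and 0.238 for SRF and actin genes. After quantile normalization 1 passed, histones, with a median of 0.45, and the others stood at 0.37, 0.14, 0.10, 0.21 (autophagy and lysosome) and 0.09 (SRF and actin). Without 6 h replicate 1, metallothioneins, histones and SRF and actin genes stood at 0.21, 0.16 and 0.08, against 0.41, 0.26 and 0.20 without 6 h replicate 2, so these 3 lists leaned more on 6 h replicate 1. By the blocked medians, the make-up of the groups could explain a part of the shift in each of the 6 lists except SRF and actin genes. The median of SRF and actin genes was 0.23 without the block and 0.238 with it, so their lost call does not speak for the make-up. Signal distribution could explain a part in all but histones and autophagy and lysosome genes. The ATF4 list stood at 0.224 with the block and 0.20 after quantile normalization, so both could explain a part of its shift as well. A response between 6 h and 12 h is not excluded.

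Among the 5 treated arrays, 3 of the 23 genes checked had 1 array far from the others: RELT with 104.8 and PPP6R2 with 122.8 on 6 h replicate 2, and CDKN1A with 283.5 on 6 h replicate 1. The cause was not tested.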

How the results depend on the processing

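The fits without both replicate 2 arrays and with array weights were chosen after the result was seen, and the other settings were planned. No gene passed in any setting. With array weights, 360 genes at 6 h, 634 at 12 h, 106 at 12 h against 6 h and 2384 in treated cells had an unadjusted p under 0.05. With the block as well these were 371, 1087, 314 and 1123, where 603 were expected by chance. The count of higher lists, 9 at 12 h against untreated, 7 at 12 h against 6 h and 2 in treated against untreated, was 0, 0 and 0 with an estimated correlation, 1, 2 and 0 after quantile normalization, 14, 13 and 6 without a filter, 2, 1 and 1 with the block, and 1, 1 and 1 without both replicate 2 arrays (1 at 12 h against each of the others with the block as well). At 6 h against untreated, 1 list was higher and 1 lower with the block, with or without the replicate 2 arrays, against 0 and 0. Apart from these list calls and those of ICAM1 and ACTB within their lists, the block changed no other call. Leaving out 1 array, higher lists ran from 0 to 6 at 6 h, 0 to 14 at 12 h, 0 to 12 at 12 h against 6 h and 0 to 7 in treated cells, and lower lists from 0 to 5, 0 to 1, 0 to 0 and 0 to 3. The largest changes of dim genes shrank in some planned settings, arrays left out aside. BAZ2B-AS1 shrank to as little as -0.95 at 6 h, KLC4 to 0.92 and OTULIN to 0.47 at 12 h. GABRR2 shrank to -1.11 at 12 h against 6 h and GPR160 to -0.91 in treated cells. Signs turned in genes that had not passed. Quantile normalization gave DDIT3 0.23 at 12 h and, at 12 h against 6 h, TXNRD1 -0.03, GCLM -0.06 and HSPA5 -0.02. Median centring, which moved the median of all genes to 0.66, 0.65 and 0.27 in the 3 comparisons that follow and so fixed these signs, gave CDKN1A 0.38 and DDIT3 0.42 at 12 h, CDKN1A 0.01 and TRIB3 0.34 at 12 h against 6 h, and MDM2 0.11 in treated cells. Averaged probe sets gave PPP6R2 -0.14, TXNRD1 -0.11 and SHMT2 0.19 at 6 h; MDM2 -0.78, TXNRD1 -0.32, ATF3 -0.33, ASNS -0.03, E2F2 -0.67 and NDUFS4 -0.38 at 12 h; MDM2 -0.28, TXNRD1 -0.21, ATF3 -0.63 and ASNS -0.27 at 12 h against 6 h; and PPP6R2 -0.13, BAX -0.04, TXNRD1 -0.19 and CARS1 -0.02 in treated cells. The block gave BAX -0.08 at 12 h and -0.03 in treated cells, and at 12 h against 6 h BAX -0.07, PMAIP1 -0.05, TXNRD1 -0.06, GCLM -0.01, TRIB3 0.05 and HSPA5 -0.04. Without both replicate 2 arrays the G1/S list stood at -0.01 at 12 h, with and without the block. With 1 array left out, ranges that crossed 0 were, at 6 h, BAX -0.32 to 0.33, PMAIP1 -0.30 to 0.59, HMOX1 -0.12 to 0.39, TXNRD1 -0.02 to 0.39, GCLM -0.02 to 0.22, SLC7A11 -0.27 to 0.28, ATF3 -0.02 to 0.54, TRIB3 -0.17 to 0.79 and the ribosomal list -0.02 to 0.28. At 12 h they were MDM2 -0.05 to 0.34, BAX -0.06 to 0.50, PMAIP1 -0.54 to 1.31, TXNRD1 -0.14 to 0.72, DDIT3 -0.56 to 0.24, TRIB3 -0.16 to 0.33 and the G1/S list -0.01 to 0.31. At 12 h against 6 h they were BAX -0.09 to 0.51, PMAIP1 -0.73 to 1.11, HMOX1 -0.11 to 0.58, TXNRD1 -0.30 to 0.56, TRIB3 -0.71 to 0.26 and HSPA5 -0.14 to 0.30, and in treated cells CDKN1A -0.09 to 0.24, MDM2 -0.25 to 0.04, BAX -0.21 to 0.29, PMAIP1 -0.23 to 0.65 and TRIB3 -0.04 to 0.44.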

Other observations

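The counts of genes over 2-fold in several pairs, the genes named from them and the tests of the patterns below were chosen after the result was seen, and the splits of the arrays were planned.

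Within the pairs of same-numbered arrays, interferon-stimulated genes (16 tested) had medians of -0.24, -0.07 and -0.17 at 6 h and -0.30 and -0.11 at 12 h. The list did not pass (adjusted p = 0.065 at 12 h, and 0.0798 with the block in treated against untreated cells). Cholesterol genes had medians of -0.11, -0.12 and -0.16 at 6 h and 0.04 and -0.11 at 12 h. SRF and actin genes ran from -0.39 and -0.09 to 0.22 in the 6 h pairs and stood at 0.17 and 0.11 at 12 h. Over 2-fold higher in all 5 pairs were 4 genes, and 0 were lower, although 6 h and 12 h pairs of the same number share an untreated array and no expected count was computed: CYP4B1 (log2 1.14 to 2.84), ICAM1 (1.17 to 2.77), LENG9 (1.58 to 2.62) and NEMP2 (1.12 to 2.06). All 4 were dim, with a mean log2 signal of 4.33 to 4.58.

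ATF4 and amino acid response genes rose at 12 h. The call was lost with camera at an estimated correlation (adjusted p = 0.373, and 0.243 with the block), a setting not run on simulated data. A hypothesis, not tested further here, is that the compound triggers the amino acid response. Not all members moved with it, with DDIT3 at -0.16 and TRIB3 at 0.09, and ASNS turned to -0.03 with averaged probe sets. The untreated arrays carry no time in the labels and serve both treated groups, so a change over time cannot be told from one due to the compound. Untreated arrays taken at 12 h would be needed to decide. The make-up of the groups did not explain the shift against untreated cells, since the median was 0.336 with the block. Signal distribution could explain a part but not all of it. After quantile normalization the median was 0.27 (camera adjusted p = 0.00074 at the preset correlation). Against RNA quality of 12 h replicate 1 stand the median of 0.277 in the other pair and that of 0.36 without this array, but both rest on a single 12 h array, which keeps that explanation open. On 12 h replicate 1 the 3′ to 5′ ratio was 2.29 for ACTB but 1.038 for GAPDH.

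In the 12 h pairs, 39 genes were over 2-fold higher in both and 41 lower in both, where 9.95 and 9.54 were expected if the pairs were independent, and in the 3 pairs of 6 h 10 were higher and 4 lower where 1.48 and 1.25 were expected. Against the 80 genes of the 12 h pairs, 62 went over 2-fold in opposite ways, a ratio of 1.29, and other pairs of pairs had ratios from 0.818 to 1.37. The expected counts treat all genes as equally likely to pass 2-fold, so noisy dim genes can exceed them. In the 6 h pairs taken 2 at a time, 220, 77 and 61 genes went the same way and 247, 88 and 69 opposite ways. With a ratio of 1.29, a response shared by both 12 h arrays and the noise of dim genes could each be the source, and neither was told from the other. None of the genes over 2-fold the same way in both 12 h pairs was bright, with 0 above a mean log2 signal of 9. Over the 2276 genes above that signal, differences in the 12 h pairs correlated at r = 0.38. Other pairs without a shared array had -0.22 to 0.31. Over all tested genes r was 0.12, against -0.04 to 0.09 (genes are not independent replicates).

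The labels were also exchanged. Of 56 splits of the 8 arrays into 5 and 3, all 56 gave as many genes as the real one, which with a real count of 0 was fixed beforehand and decides nothing, and the highest other gave 550, with the replicate 3 arrays against the rest, which points to a structure of the samples by replicate number. For genes at an unadjusted p under 0.05, 48 splits had as many as the real 94 (highest other 3580), and for lists 45 had as many as the real 2 (highest other 16). Among the 18 splits that part the numbers as the real one does, the highest others were 0, 248 and 5, and 10 of the 18 reached the real count of unadjusted genes and 10 that of lists. At 6 h the 10 splits are too few for a share under 0.05: all 10 had as many genes as the real 0 (highest other 0), 10 as many as the real 79 unadjusted (highest other 2689) and 10 as many lists as the real 0 (highest other 12), where counts of 0 again decide nothing. Among the 4 of these that part the 3 numbers, the highest others were 0, 144 and 4, so the larger values follow the replicate numbers.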
